A study of Mus musculus with 5 samples.

How the data were processed

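RNA of Erbb2-transfected and parental NIH3T3 mouse fibroblasts was compared on 5 arrays carrying spotted cDNA probes, with both cell lines hybridised to each array in different dyes. The labels assign 3 arrays to preparation A (A1, A2 and A3) and 2 to preparation B (B1 and B2). NIH3T3 cDNA carried Cy5 on A1, A2 and B1, and the dyes were exchanged on A3 and B2. Per the labels, the authors scanned the arrays with a GenePix scanner, subtracted the background from the mean spot intensities and scaled each array so that the median ratio became 1. The rule by which the authors left values empty is not given in the sources used here.

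The deposited values are log2 ratios of the dyes, as far as the values themselves show. Their medians lay between -0.0017 and 0.0071. On A2, 58.6% of the values equalled a constant plus the log2 of a ratio of whole numbers up to 300, within 6e-07, against 1.45% after the constant was shifted. The other arrays had lower shares, from 19.1% (B1) to 49.6% (B2), against 1.70% and 1.39% after the shift. Under a natural logarithm the share was 2.48% on A2, 1.97% on B1 and 2.10% on B2, so base 2 was used. Arrays of opposite dye orientation correlated negatively as deposited, with r across probes between -0.17 and -0.54, so the values had not been turned for the exchange of dyes. Which dye is the numerator is not given in the sources used here. Cy5 over Cy3 was taken, because Cy5 is the first channel of every array in the labels. The direction is therefore likely rather than settled, and under the opposite reading every rise becomes a fall of the same size.

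Values were turned to Erbb2-transfected over NIH3T3. Of the 20205 probes, 11723 had 1 gene symbol in the platform annotation, 806 had several and 7676 were not listed there and remained unnamed. The Entrez identifiers of 11590 probes were found in a mouse gene table of assembly GRCm38.p6, which changed 0 symbols. Probes of 1 gene symbol were averaged to a gene, and every other probe was kept as its own feature, which gave 18151 features. Of the tested genes, 1018 had more than 1 probe. Where such probes had values on different arrays, the spread between preparations can in part be one between probes. For each preparation, arrays of one dye orientation were averaged first and then the orientations, so that an additive dye effect cancelled. The 4892 features with a value in both orientations of both preparations were tested, of which 3134 were genes. Arrays held values for 5368 (A1), 11348 (A2), 7261 (A3), 17463 (B1) and 13109 (B2) probes. The number of arrays limits the precision.

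The 2 preparation means were tested against 0 with lmFit and eBayes in limma 3.58.1 under R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The prior degrees of freedom were 10.2. Dye effects and differences between preparations were tested with limma on the 5 arrays. Gene lists fixed before the data were examined were tested with camera in limma at a preset correlation of 0.01, for the 16 of 23 lists with 5 or more tested genes. The lists, tests, gene rule and most alternatives were likewise fixed before the data were examined. Genes named are the 12 largest rises and the 12 largest falls among genes past the threshold with 1 sign on every array with a value, and up to 4 members past the threshold per list. Where no member passed, up to 2 members with 1 sign on all arrays are given as values. All measured ERBB receptor genes were to be named. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

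The procedure was tested on simulated data with the real pattern of missing values, in 20 draws of 4892 features of which 200 were changed. In the comparison of cell lines, changes of 0.5, 1 and 2 on the log2 scale were recovered in 10.4%, 84.9% and 100% of features on average. On average 10.5% of the calls were false, with a range over draws from 1.65% to 21.1%, which is above the nominal 5%. With 5 arrays and a dye term, the average was 4.21%. The cell line comparison was simulated without a preparation effect, so this lower rate may not hold where arrays of 1 preparation share one. Preparation differences of 1 and 2 were recovered in 6.12% and 60.8% of features, so that test missed most differences of 1 or less. On 1 set of unchanged data, 0 features were called, and 3.5% of 200 random lists had a camera p under 0.05. Features were simulated independently of each other, so this share does not apply to lists of correlated genes.

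The alternatives covered the unit of replication, the dye term, centring, scaling and quantile normalization, missing and extreme values, the summary of probes, the variance estimate, the threshold and leaving out each array. Leaving out spots with ratios of small whole numbers, averaging only probes measured in both dye orientations of both preparations, an estimated correlation on 5 arrays, and estimated correlations taken as known were added after seeing the data. No probe named for Erbb2 or Erbb4 alone had a value on any array, so neither gene was analysed and the transfected gene could not be checked.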

Results

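Gene expression was compared between NIH3T3 cells, an immortalised mouse fibroblast line, and NIH3T3 cells that stably overexpress the human receptor tyrosine kinase ERBB2 (HER-2/neu) from a viral promoter. Both lines were hybridised together on 5 two-colour cDNA arrays, 3 from preparation A and 2 from preparation B, with the dyes exchanged on 1 array of each preparation. Values are log2 ratios of Erbb2-transfected over NIH3T3 cells, given as the mean ± SD of the 2 preparations. The direction is likely and rests on Cy5 being the numerator. Nothing in the labels says whether the preparations were separate cultures, so the spread between these samples may be technical. The p-values of limma rest on it only in part, with 1 residual degree of freedom per feature against 10.2 prior ones pooled over features. Those of camera compare list members with other genes. No p-value here extends beyond these samples.

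Several of the largest falls were in genes of the extracellular matrix list, of which 10 of 24 tested fell and 14 did not pass (list adjusted p = 4.73e-12 by camera; adjusted p = 0.664 with an estimated correlation). Col1a1 and Col1a2, the chains of type I collagen, had log2 ratios of -4.93 ± 0.75 and -3.97 ± 0.14 (SD, n = 2). This SD does not show the spread between dye orientations, which were averaged first: Col1a2 had -2.63 on A2 against -4.98 on A3. Probes taken alone also lay apart, at -5.37 and -3.66 for Col1a1 and at -4.63 and -3.35 for 2 of the 3 probes of Col1a2. Lox, which crosslinks collagen and elastin, had -4.73 ± 1.26, although its 2 probes taken alone lay far apart, at -5.61 and -2.01. Fn1, the fibronectin gene, had -4.61 ± 0.13. Among genes past the threshold with 1 sign on every array with a value, the largest rise was that of Serpina12, a serpin known as vaspin, at 3.28 ± 0.08. Rises of Sox9 and Klf5, both transcription factors, were smaller, at 1.90 ± 0.42 and 1.89 ± 0.56.

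In all, 332 of 4892 features passed limma's test at an adjusted p under 0.05, of which 110 were higher and 222 lower in Erbb2-transfected cells. These included 235 genes, 68 higher and 167 lower. Changes of 2-fold or more were found for 185 features, 50 higher and 135 lower. On every array with a value, 300 of the 332 features had the same sign. The number of calls ranged widely with the processing, with 564 when only probes measured in both dye orientations of both preparations were averaged, 187 after scaling the arrays to equal spread and 218 without array B1. In simulated data, the test made 10.5% false calls on average, above the nominal 5%.

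**Figure D1:**
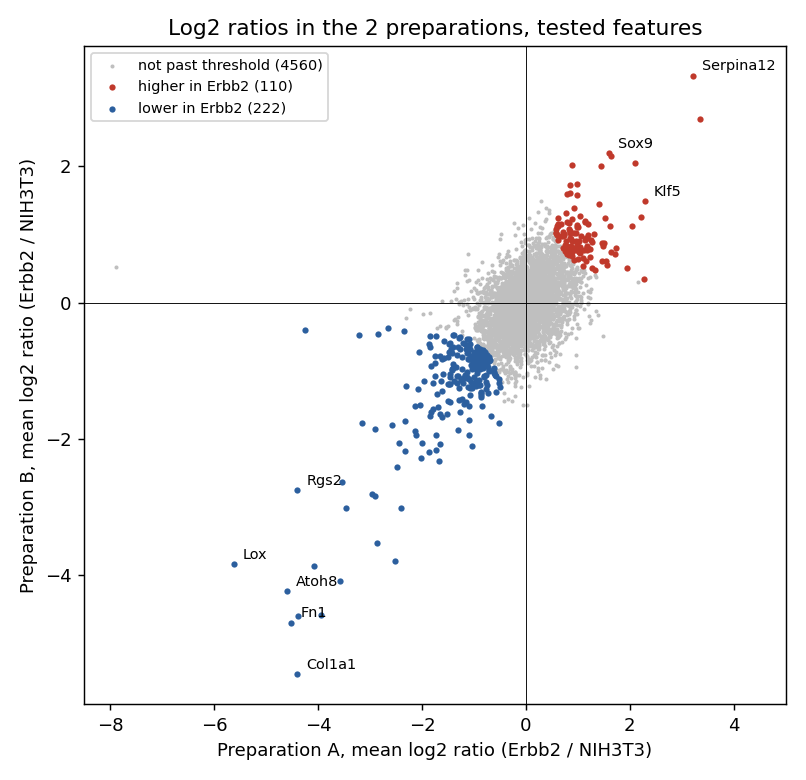
Mean log2 ratio of each tested feature in preparation A (horizontal axis) and preparation B (vertical axis), with the 110 features called higher in red, the 222 called lower in blue and the others in grey. The preparation means correlated with r = 0.60 across features, which are not independent replicates, and Col1a1, Lox and Fn1 lie at the lower left.

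Besides the collagens, Lox and Fn1, the largest falls included Fbln5 and Fbln2, which encode fibulins of elastic fibres and basement membranes, at -3.84 ± 0.35 and -3.20 ± 0.47. Atoh8, a basic helix-loop-helix transcription factor, had -4.42 ± 0.25 (adjusted p = 3.81e-07). Rgs2, a regulator of G protein signalling, had -3.58 ± 1.17, and Ptgis, the prostacyclin synthase gene, had -2.87 ± 0.05. Among the rises, Prkg2, a cGMP-dependent protein kinase, had 1.74 ± 0.68, and Capg, an actin-capping protein, had 1.73 ± 0.39. Stbd1, which binds glycogen, had 1.59 ± 0.65, with array A3 at 2.96 apart from the other arrays. Cd44, the hyaluronan receptor, had 1.37 ± 0.34, and Ndrg1 had 1.36 ± 0.54. Oaf, Fip1l1, Wwc1 and Dnah6 rose by 1.43, 1.38, 1.27 and 1.23. Without array A3 or without array B1, Wwc1 and Dnah6 no longer passed.

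**Figure D2:**
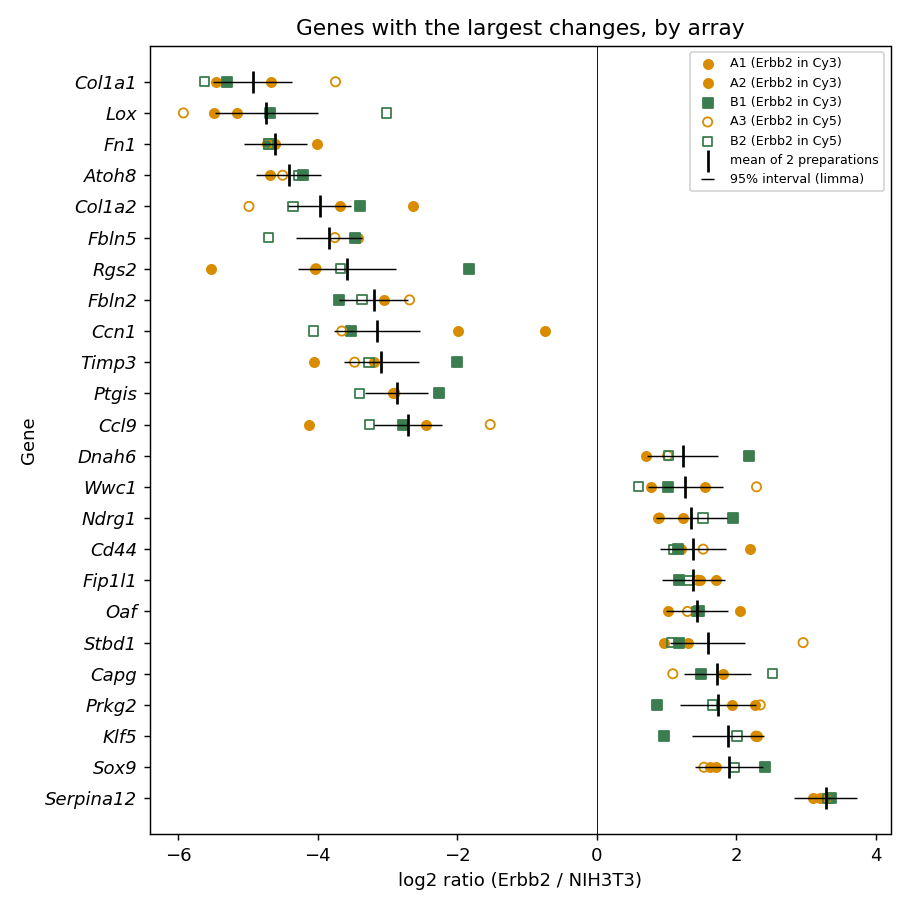
Log2 ratios on each array for the 12 genes with the largest falls and the 12 with the largest rises, with preparation A as circles, preparation B as squares and open symbols for arrays with Erbb2-transfected cells in Cy5. Vertical ticks are the means of the 2 preparations and horizontal bars limma's 95% intervals; Serpina12 lies between 3.09 and 3.36 on all 5 arrays.

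Of the 24 tested genes of the extracellular matrix list, 10 fell, 0 rose and 14 did not pass over all features. Adjusted over the list alone, 11 fell and 1 rose. The remaining members that fell, named after their values were seen, were Sparc, Pcolce, Serpinh1 and Ltbp3, at -2.46, -1.83, -1.58 and -0.87. Col3a1, another fibrillar collagen, had 0.51 ± 0.99 and did not pass. The list was lower as a whole by camera (median -0.56, mean -1.44, adjusted p = 4.73e-12). It was not called when camera estimated the correlation (adjusted p = 0.664 with an estimated correlation). On 2 preparation means that setting leaves 1 residual degree of freedom, so this p does not show that correlation among the genes accounts for the call. The estimate for this list was -0.0362 on preparation means and 0.0837 on 5 arrays, against the preset 0.01, and with 0.0837 taken as known the adjusted p on 5 arrays was 0.00124 rather than 1.55e-07. The limit of 1 degree of freedom holds for each p with an estimated correlation below. The estimates for actin (0.377), glycolysis (0.2), interferon (0.143) and endoplasmic reticulum stress (0.0476) on preparation means lay above the preset value, and these 4 lists were also not called with the estimates taken as known.

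The extracellular proteolysis list was also lower (adjusted p = 0.01; 0.664 as the adjusted p with an estimated correlation), with 4 of 11 tested members falling and 0 rising; 7 fell and 1 rose adjusted over the list alone. Timp3, an inhibitor of metalloproteinases bound to the matrix, had -3.09 ± 0.65. Serpinf1, Mmp2, which degrades basement membrane collagen, and Adamts1 had -1.16, -1.02 and -0.96. The fall of Adamts1 was not called without array A3 or without array B1, and that of Serpinf1 was not called without B2.

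In the list of actin cytoskeleton, contractility and focal adhesion, 5 of 22 tested members fell and 1 rose (adjusted p = 0.00267; adjusted p = 0.681 with an estimated correlation). Adjusted over the list alone, 7 fell and 1 rose. The 22 members averaged -0.27 in preparation A and -0.75 in preparation B, a difference that was not tested. Ccn1, a matricellular protein, had -3.15 ± 0.90, Itgb5, an integrin subunit, had -1.59 ± 0.39, and Cald1, the caldesmon gene, had -1.41 ± 0.44. Ankrd1 had -1.14 ± 0.88 and was not called without array B2. The 2 probes of Ccn1 taken alone had -3.50 and -3.32, and those of Ankrd1 -1.74 and -1.15. Each gene value thus lies outside the range of its probes, which were not measured on the same arrays. Csrp2, named after its value was seen, rose by 1.00.

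Of 9 tested cytokine, chemokine and inflammation genes, 4 fell and 0 rose (adjusted p = 0.0012; adjusted p = 0.664 with an estimated correlation). Adjusted over the list alone, 4 fell and 1 rose. Ccl9, a chemokine, had -2.71 ± 0.43, and Csf1, the macrophage growth factor, had -1.95 ± 0.31. Igfbp4 and Igfbp6, which bind insulin-like growth factors, had -2.19 ± 0.55 and -0.94 ± 0.65. Without array A3, B1 or B2, Igfbp6 did not pass.

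The interferon response list was lower (adjusted p = 0.01; adjusted p = 0.664 with an estimated correlation), with 3 of 8 tested members falling and 0 rising, and 5 falling when adjusted over the list alone. Ifitm1, Trim25 and Ifi35 had -1.10 ± 0.18, -0.92 ± 0.19 and -0.79 ± 0.10. Trim25 had 0.10 on A2 against -1.60 on A3, and Ifi35 had 0.10 on B1 against -1.82 on B2. Neither of these was below 0 on every array, and the SD of preparation means does not show this spread between dye orientations. The Ifitm genes are close relatives in sequence, so their separate values are uncertain. Of the 8 tested members, 6 lay below 0, among them Ifitm2 and Ifitm3, which did not pass. Stat2 and Ifit3, named like the following genes after their values were seen, lay above 0, at 0.18 and 0.25. Outside the test, Mx2, Oas2, Ifi203 and Rsad2 were above 0 on every array with a value, and Irf1 and Gbp4 below 0. The fall was thus not shared by all interferon genes measured. Trim25 was not called without A3 or B1, nor Ifi35 without B2. The list was not called without array A2 (adjusted p = 0.073) or A3 (adjusted p = 0.128). In these settings 6 and 13 members were tested rather than 8, so members and arrays changed together. Of the genes of MHC class I antigen presentation, 4 were tested, too few for the list test. H2-Q10 fell by 1.11 ± 0.07, although its sequence is close to that of other class I genes, and 1 member fell when adjusted over the list alone. On B1 H2-Q10 had -0.44 against -1.89 on B2, a spread that its SD does not show. Without array B2, H2-Q10 was not called. B2m, Canx and Psmb10 did not pass, at -0.21, -0.24 and -0.22. Among untested members, also named after their values were seen, Tap1, H2-M3, Psme2 and Calr were below 0 on every array with a value. Psme1 had both signs, and Psmb8 had 0.01 on A2 alone.

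Of 5 tested genes of glycolysis and lactate export, 3 fell, namely Pfkp, Ldha and Aldoa, with -1.38 ± 0.64, -0.98 ± 0.07 and -0.89 ± 0.03, and the same number fell when adjusted over the list alone. Ldha was not called without array B2, nor Aldoa without A3 or B1. Between dye orientations Aldoa spread more than its SD shows, with -0.40 on A2 against -1.27 on A3. The list was lower (adjusted p = 0.017; adjusted p = 0.664 with an estimated correlation) but was not called without array A3 (adjusted p = 0.119) or B1 (adjusted p = 0.0887). Of 15 genes of endoplasmic reticulum stress and amino acid response, 4 fell and 0 rose, and 5 fell when adjusted over the list alone. Pdia6 and Ero1a, which form disulphide bonds in secreted proteins, had -2.37 ± 0.74 and -1.77 ± 0.77. Ddit4, an inhibitor of mTOR signalling, had -1.46 ± 0.23, and Dnajb11, a chaperone, had -0.77 ± 0.11 and was not called without A3, B1 or B2. The 15 members averaged -0.78 in preparation A and -0.27 in preparation B, a difference that was not tested. Of these members, 10 were lower in A than in B and 5 higher, among them Psat1 with 0.27 against -0.22 and Shmt2 with 0.41 against 0.03. Hsp90b1, Manf and Pdia4, named like these after their values were seen, did not pass and had -1.18, -1.38 and -1.71 in preparation A against 0.48, 0.17 and -0.37 in B. Outside the test, Ddit3 had -3.26 and -3.08 on A1 and A2 against 0.08 and -0.33 on B1 and B2, and Asns had 0.77, 0.67 and 0.58 on A1, A2 and A3 against -0.88 on B2. Like Ddit3, Hspa5, Calr, Creld2 and Herpud1 were lower on A1 and A2 than on B1. Like Asns, Slc3a2 was higher on A2 and A3 than on B1. Further untested members went both ways, and all of these were chosen after their values were seen. The endoplasmic reticulum stress list was lower (adjusted p = 0.017; adjusted p = 0.664 with an estimated correlation) but was not called without array A1 (adjusted p = 0.0536) or A2 (adjusted p = 0.0624).

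**Figure D3:**
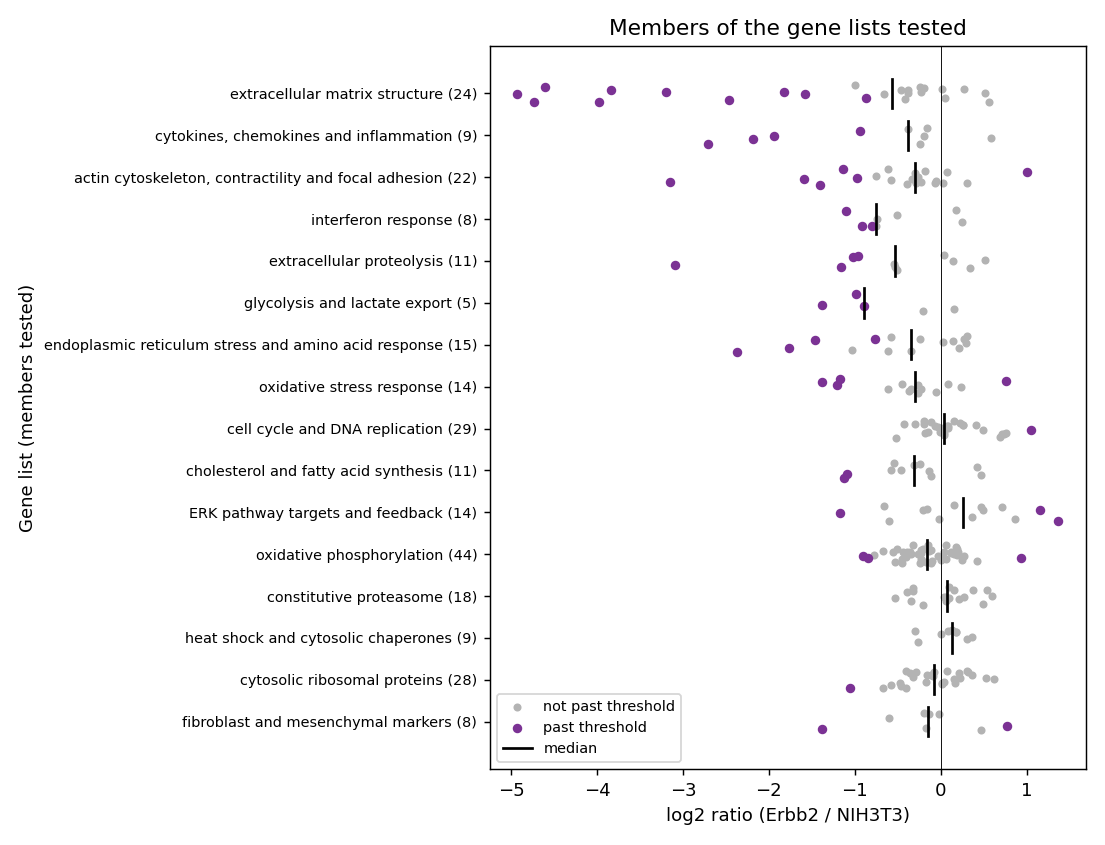
Log2 ratios of the tested members of the 16 lists tested, with members past the threshold in purple, others in grey and the median of each list as a vertical bar. Extracellular matrix genes reach from -4.93 to 0.56, with a median of -0.56.

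The other 9 lists did not pass. Among 14 targets and feedback genes of the ERK pathway, Fosl1, an AP-1 subunit, rose by 1.16 ± 0.20, Cd44 rose, and Ier2, an immediate early gene, fell by 1.17 ± 0.09 (list adjusted p = 0.076). Adjusted over the list alone, 4 rose and 3 fell. Of 29 cell cycle genes, Tk1, the thymidine kinase gene, rose by 1.05 ± 0.72 but was not called without array B2, and 4 rose when adjusted over the list alone (list adjusted p = 0.0709). This list averaged 0.40 in preparation A and -0.12 in B, and passed without array A3 (adjusted p = 0.0454) and without B1 (adjusted p = 0.0315). Without A3, 38 of its members were tested rather than 29. Of 14 oxidative stress genes, Aldh3a1, Fth1 and Gstm1 fell, with -1.39 ± 0.95, -1.20 ± 0.17 and -1.17 ± 0.96, and Mt2 rose by 0.76 ± 0.06 (list adjusted p = 0.0502). None of these 4 was called without array B2, nor Mt2 without A3 or B1. On B2 itself Gstm1 lay above 0, at 0.38. Among the 14 genes, 4 fell and 1 rose when adjusted over the list alone. That list passed without array A2 (adjusted p = 0.0278), A3 (adjusted p = 0.0162) or B2 (adjusted p = 0.0446). Fads2 and Ebp, of lipid and cholesterol synthesis, fell with -1.12 and -1.09, and both did so adjusted over the list alone (11 tested, list adjusted p = 0.0721), with Ebp not called without B2.

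Of 44 genes of oxidative phosphorylation, Cox6a2 and Ndufv1 fell and Atp5d rose, with -0.91, -0.85 and 0.94, and adjusted over the list alone 3 fell and 1 rose (list adjusted p = 0.24). Cox6a2 was not called without array B2, Atp5d without A3 or B1, and Ndufv1 without any of these 3. Rpl15 fell by 1.05 ± 0.06 as 1 of 28 ribosomal protein genes, and 1 fell adjusted over the list alone (list adjusted p = 0.795). Of 18 proteasome and 9 heat shock genes, 0 passed over all features and 0 adjusted over the list alone (list adjusted p = 0.361 and 0.382). Psmc2 and Psma2 had 0.60 and 0.54, and Hspa9 had 0.18. Among 8 fibroblast and mesenchymal markers, Gas1, a growth arrest gene, fell with -1.38 ± 1.37 and Pi16 rose by 0.77 ± 0.22, which was not called without A2, A3, B1 or B2 (list adjusted p = 0.798). Adjusted over the list alone, 2 fell and 1 rose. The median and mean of the 8 markers lay at -0.15 and -0.16. On the 5 arrays the list's direction was upward, but only the 5 markers with values on all arrays entered, so members and fit changed together.

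Markers of other cell types gave no call in limma's test over all features or adjusted over the list alone. Krt19 (epithelium) had 0.19, Flt1 (endothelium) 0.16 and Tnnt3 (skeletal muscle) 0.21. The 4 macrophage and leukocyte markers tested had a median of 0.07, as did the 3 adipocyte markers. Of the ERBB receptor genes, Egfr was measured by a pair of probes on B1 alone, at -0.16 and 0.59. Erbb3 had -0.94 on A2, -0.06 on B1 and -0.31 on B2. Both were outside the test. Shc1, an adaptor of the receptors and the 1 tested member of that list, had -0.03 ± 0.30.

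A dye effect, which exchanging the dyes separates from the difference between cell lines, was found by limma for 7 of 4892 features at an adjusted p under 0.05 and for 633 at an unadjusted p under 0.05. The named genes among them, chosen after their values were seen, were Cchcr1, Dst and 4933404O12Rik. Cchcr1 had 3.52, 3.58 and 3.38 on A1, A2 and B1 but -0.62 and -1.62 on A3 and B2. The number of features was 31 without array A1, 2 without A3 and 2 without B2.

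Between preparations A and B, 1 feature differed by limma's test, and 330 did so at an unadjusted p under 0.05. That unnamed probe had -8.30, -6.91 and -8.16 on A1, A2 and A3 and 0.46 and 0.58 on B1 and B2 (adjusted p = 2.09e-08). The number was 25 without array A1 and 33 without A2. In simulated data, differences of 2 on the log2 scale were recovered in 60.8% of features and differences of 1 in 6.12%, so most differences of 1 or less would be missed.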

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

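All tests of explanations in this part were chosen after the results were seen. In 5 of the 63 named genes, 1 array stood apart from the others, and chance does this in about 5% of genes. Fn1 had -4.01 on A2 against -4.72 to -4.61 on the other arrays. Igfbp4 had -1.13 on B1 against -2.69 to -2.46. Flt1, which was not called, had 0.53 on A2 against 0.01 to 0.07. Stbd1 had 2.96 on A3 against 0.96 to 1.31, and Klf5 had 0.97 on B1 against 2.01 to 2.30.

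The lower values of extracellular matrix genes were set against technical explanations. Dye bias would need a mean at or above 0 in 1 dye orientation, but the 24 tested members averaged -1.52 with Erbb2-transfected cells in Cy5 and -1.37 in Cy3. Without ratios of whole numbers up to 100, the 19 members still tested averaged -1.72, all 10 called members among them, so the falls do not rest on the 11 spots left out. A spot is left out only if both numbers are 100 or less, so a large fall with 1 bright channel stays. Noise in the dimmer channel is therefore not tested and stays open. The authors' median scaling adds 1 constant per array, which moves all features alike and cannot change the gap between members and other features. The members averaged 1.23 or more below the other tested features on every array (-1.23 on B2, the nearest to 0). Camera tested the same contrast, so this gap is no separate check. A biological effect of ERBB2 may account for the pattern as a hypothesis, but a difference between a selected transfected line and its parent, or in density or passage, was not tested and stays open.

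Arrays of the same dye orientation resembled each other more (mean r 0.49 over 4 pairs) than arrays of opposite orientation (0.33 over 6 pairs). Dye bias of the probes is a candidate explanation. The covariance shared by orientation was 0.0442 (95% interval 0.0361 to 0.0518), against 0.241 shared by cell line, but this measures the same resemblance and does not test its cause. Shared preparation cannot be the whole cause, because among pairs from different preparations the mean r was 0.242 higher for the same orientation, although preparation also shared a covariance of 0.066. Among 1748 probes with no ratio of whole numbers up to 100, this covariance by orientation was 0.0447, which argues against those spots as the cause. That limit covers 6.05% (B1) to 20.2% (A2) of values, and a limit of 300 covers 19.1% (B1) to 58.6% (A2). Dim spots above the limit of 100 thus stay open. No biological explanation was tested.

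The unnamed probe far below 0 in preparation A kept its value on the array with exchanged dyes, at -8.16, which argues against dye bias. A swap of the RNAs throughout 1 preparation is argued against by the correlation of the preparation means (r = 0.601 across features). A wrong RNA from similar cells could also leave a positive correlation, so that explanation stays open. A difference between cultures, or a contaminant of one RNA, stays open and was not tested, and the test for other differing features had little power.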

How the results depend on the processing

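Some alternatives were chosen only after seeing the data, and are named as added. Against 332 features (110 higher, 222 lower), 5 arrays with a dye term called 170 higher, and preparation as a random block 509 (198 higher). The consensus correlation of that block was -0.0489, so it does not discount what arrays of 1 preparation share. Scaling called 187 (60 and 127), leaving out the extreme 1% of probes 182 (47 and 135), requiring 2-fold 185 (50 and 135), an adjusted p under 0.1 548 (222 higher), and probes on their own 544 (210 and 334). Added settings gave 564 (228 and 336) with only probes measured in both dye orientations of both preparations and 201 (49 higher) without ratios of whole numbers up to 300, where 1299 features were tested. Leaving out 1 array gave 218 (B1) to 498 (A1) features, 58 (B1) to 192 (A1) higher and 152 (B2) to 306 (A1) lower. Dye effects ranged from 2 (A3 or B2 out) to 31 (A1 out), and preparation differences from 1 to 33 (A2 out; 25 with A1 out). The share of calls that were lower stayed between 59.5% and 75.6%.

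Of the 7 lists called, 0 were called with an estimated correlation, with adjusted p of 0.664, or 0.681 for actin, on preparation means. On 5 arrays, an added setting, these were 0.282, or 0.607 for actin and endoplasmic reticulum stress, so 0 lists were called in both. These settings leave camera 1 and 3 residual degrees of freedom, which by itself raises the p, so they do not show that correlation accounts for the calls. An added setting took the estimated correlations as known, with negative ones as 0, and so kept the degrees of freedom but not the uncertainty of the estimates. It called 3 lists on preparation means and 4 on 5 arrays. Matrix, proteolysis and cytokines were called in both, and oxidative stress on 5 arrays (0.0449). On preparation means the estimates for the first 3 were negative (-0.0362, -0.0182 and -0.111) and were taken as 0, below the preset 0.01. For these lists that setting was more lenient than the main test and is no check. The same holds for proteolysis on 5 arrays, where its estimate was -0.0552. The adjusted p was 0.0815 and 0.0589 for interferon, 0.352 and 0.524 for actin, 0.0956 and 0.0589 for glycolysis, and 0.0815 and 0.524 for endoplasmic reticulum stress. With features complete on all arrays and probes, 3 lists were called, and the adjusted p was 0.0616 for interferon, 0.0507 for proteolysis and endoplasmic reticulum stress, 0.178 for actin and 0.022 for oxidative stress. Leaving out extreme probes, which removes the most changed members, left 1 list, with 0.165 for matrix, 0.0937 for actin and 0.156 for proteolysis, endoplasmic reticulum stress and cytokines. Added settings without whole-number ratios gave 0.316 for interferon and 0.0809 for endoplasmic reticulum stress up to 100, and up to 300 left 3 lists, with 0.351 for actin and 0.0929 for glycolysis and endoplasmic reticulum stress. For endoplasmic reticulum stress the adjusted p was 0.0547 with plain means, 0.108 after scaling and 0.204 by camera on 5 arrays. Oxidative stress passed after centring (0.0487), quantile normalization (0.0351) and on 5 arrays (0.0327), as did the cell cycle on 5 arrays (0.043). With fry, actin and endoplasmic reticulum stress had 0.145 and oxidative stress 0.0197. Leaving out 1 array gave 6 to 8 lists, with adjusted p from 0.0065 (A1) to 0.128 (A3) for interferon, 0.00608 (B2) to 0.119 (A3) for glycolysis, 0.00134 (A3) to 0.0624 (A2) for endoplasmic reticulum stress, 0.0162 (A3) to 0.0887 (B1) for oxidative stress and 0.0315 (B1) to 0.381 (B2) for the cell cycle.

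Of 59 named genes past the threshold, 46 could be tested without each array in turn, and 29 of these were called each time. The other 13 had no value on A1 and could not be tested without A2, and 8 of them were called without each of the other arrays. The call was lost for 16 without B2 (adjusted p 0.0508 to 0.315), 11 without A3 (0.0506 to 0.232), 11 without B1 (0.0556 to 0.459) and 1 of the 46 tested without A2 (0.0656). Leaving out A3 or B1 gives the same mean by construction, since the dye effect is then taken from the other preparation, so these are not separate checks. Scaling ended 15 calls and quantile normalization 6. No called gene or list reversed in these alternatives. Except where an alternative tested fewer features, the cause was not tested. Signal over background was not used here, so the share of dim spots is known only from whole-number ratios. Each ratio already pairs the cell lines on 1 array, so the main test is a paired one.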

Other observations

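Outside the test, 8 of 7104 features measured in both dye orientations were 4-fold or more apart on every array with a value, 7 lower and 1 higher in Erbb2-transfected cells. They were chosen after their values were seen and carry no test. Of 15 untested members of the matrix list with values in both orientations, 10 were below 0 on every array with a value, 1 was above 0 and 4 had both signs. The 8 features include 3 of these members: Bgn, which encodes the proteoglycan biglycan, had -4.99 on B1 and -6.93 on B2, Col5a2 had -3.61 and -2.72, and Ogn, the osteoglycin gene, had -2.38 and -2.76. Ccn2, a matricellular relative of Ccn1, had -4.43 and -5.97. Fgf7, a growth factor of epithelial cells made by fibroblasts, had -4.32, -3.77, -5.36 and -3.13 on A1, A2, A3 and B2. The higher gene was Itgb7, an integrin subunit, with 2.95, 3.00 and 2.11 on A2, B1 and B2.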
